A study of Mus musculus with 6 samples.

How the data were processed

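RNA was measured in 6 libraries of mouse leukaemia cells, 3 labelled SLC6A6 KO and 3 labelled WT. Per the labels' protocols, mice received primary leukaemia cells carrying BCR-ABL and NUP98-HOXA9, leukaemia cells were sorted from the spleen, and RNA was extracted with a micro-scale column kit. Small amounts of total RNA were pre-amplified from the poly(A) tail with the SMARTer Ultra Low Input chemistry, and libraries were made by Nextera XT tagmentation and sequenced as single-end reads on a NextSeq instrument. The marker used for sorting is not given in the sources used here. The chemistry does not mark strand, so reads of a gene and of an overlapping antisense partner cannot be told apart. It also carries no molecular identifiers, so amplified copies of a cDNA count as separate reads, and intervals and limits on counts cover counting error only.

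The values are counts of reads per gene, deposited as whole numbers in 1 table with a column per library. Per the submitters' processing notes, fastp 0.23.1, STAR 2.7.9a, Subread 2.0.1 and featureCounts were used before deposit, and their parameters, the genome build, the annotation and the treatment of reads with several matches are not given in the sources used here. For that reason no coordinates are given. The mouse annotation GENCODE M21 served only to find which genes lie on the X and Y chromosomes, which genes neighbour Slc6a6, and the GC content and transcript length of 97.3% of the tested genes. The table holds 53819 genes, and no sample column was left unused.

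Counts were taken as deposited. Genes with low counts were removed with edgeR's filterByExpr by group (minimum count 10, minimum total count 15), which left 15232 genes. Libraries were normalised by TMM in edgeR 4.0.16 under R 4.3.3, and the groups were compared with the quasi-likelihood F test with robust dispersions and no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are given as fitted, KO over WT, and the standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes and are given as mean ± SD over 3 libraries. A group with 0 counts for a gene was set to 3 counts over its 3 libraries, which gives a lower bound for the fold, and a group with 1 to 3 counts is given as a ratio with its exact (Clopper-Pearson) counting interval at 95%. The biological coefficient of variation was 0.323. At these depths 3 counts in a library correspond to 0.0606 to 0.0700 CPM.

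The 39 gene lists cover metabolism, stress responses, growth, signalling, the leukaemia programme and markers of other blood, stromal and endothelial cells, with 870 genes of which 2 had no row in the table under the symbols used. Lists with at least 5 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry. The number of members past the gene test is given over all genes tested and adjusted over the list alone.

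Genes were named by a fixed rule: Slc6a6, then the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, then up to 4 members with the smallest p and at least 1 CPM from each list past camera, from the glycolysis, mTORC1 and taurine lists and from each marker list. On the first of these criteria 169 rises and 246 falls qualified, and 3 and 8 of them carry symbols of provisional genes, pseudogenes, clones or immune receptor segments, which were counted but not named. Other named genes are said to be chosen after their values were seen, and some genes are not reported here. The lists, the tests, the naming rule and the alternatives not said to be added later were fixed before the data were examined.

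The fitting code was tested on simulated counts for the 15232 genes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. For this comparison edgeR recovered 11.9% of genes changed 1.5-fold, 49.3% of those changed 2-fold and 63.6% of those changed 4-fold, with 2 false calls. DESeq2 1.42.0 recovered 26.9%, 62.7% and 72.7% of these genes with 47 false calls. For limma-voom the shares were 10.4%, 47.8% and 63.6%, with 1 false call. With the glycolysis list lowered 1.25-fold, camera gave an adjusted p of 1.51e-08 and called 0 other lists. Simulated genes were independent of each other, so this does not test the preset correlation. Alternatives were other scalings, other tests, other low-count filters, the replicate number as a block, each library left out in turn, and, added after seeing the data, an erythroid covariate and the removal of X and Y genes.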

Results

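Gene expression was measured by RNA sequencing in mouse leukaemia cells sorted from the spleens of mice transplanted with a leukaemia driven by the fusion genes BCR-ABL and NUP98-HOXA9, a combination used to model the blast crisis of chronic myeloid leukaemia. The labels name 2 groups of 3 libraries each, SLC6A6 KO and wild type (WT), while the title of the series speaks of a knock-down. Slc6a6 encodes the taurine transporter, and the comparison asks how its loss changes the transcriptome of these leukaemia cells. Library totals were 44902511, 44639077 and 42829294 counts in KO1, KO2 and KO3, and 49537098, 47939534 and 44950191 counts in WT1, WT2 and WT3. Between 20681 and 21694 genes had at least 1 count in a library. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom within a group lay between 36.4 and 127. The labels do not say whether the 3 libraries of a group came from separate mice or separate primary leukaemias, so p-values measure only the spread between these samples, which may be technical.

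In the libraries labelled KO, Slc6a6 was measured at 125, 132 and 133 CPM, against 151, 145 and 145 CPM in the libraries labelled WT. All 3 KO values lay below all 3 WT values, by 11.7% in the fit (log2 fold change −0.18 ± 0.07, SE, n = 3 against 3). The difference did not pass edgeR's quasi-likelihood test, with a Benjamini-Hochberg adjusted p of 0.196. Counts per gene cannot show whether part of the transcript was lost or altered, and the labels do not give the allele, so the Slc6a6 level does not check the genotype. KO and WT are used below as the labels of the libraries.

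Sex-linked genes separated the libraries along the same line as the labels. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d together had 10274 to 11236 counts in each library labelled KO, 0 in WT1 and WT2, and 1 in WT3. Eif2s3y stood at 92.5 ± 9.64 CPM (SD, n = 3) in the KO libraries, at least 4414-fold higher than the limit that a count of 0 over the WT group allows. For Uty and Kdm5d this bound was 2070-fold and 1323-fold, and for Ddx3y, with 1 count in WT, the ratio was 11762 with a 95% exact counting interval from 2111 to 464607. Xist, the RNA that silences 1 X chromosome in female cells, was at 178 ± 18.7 CPM in the WT libraries, and at 4.41, 0.305 and 0.776 CPM in KO1, KO2 and KO3. In 6 of 6 libraries sex-linked expression therefore followed the label, and every difference below is also a difference between libraries with and without Y-linked transcripts.

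**Figure D1:**
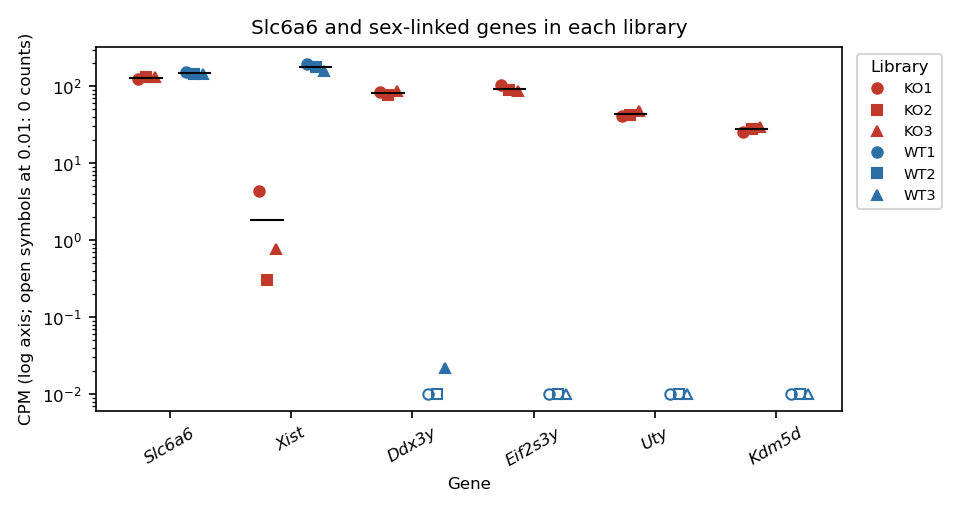
Level of Slc6a6, Xist and 4 Y-linked genes in each library, in CPM on a log axis, with a symbol per library, a bar at each group mean and open symbols for 0 counts. Slc6a6 lies between 125 and 151 CPM in all 6 libraries, while the Y-linked genes are seen in the libraries labelled KO and Xist is highest in those labelled WT.

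Of 15232 genes tested, 250 were higher and 293 lower in the libraries labelled KO at an adjusted p below 0.05 in edgeR's quasi-likelihood test, of which 171 and 181 differed by a log2 fold change of at least 1. After the Y-linked genes, the largest rises among genes past the naming rule were those of Adgrg7, an adhesion G protein-coupled receptor, with 14.6 ± 6.91 CPM in KO and 0.0562 ± 0.0973 in WT, and Rbm44, an RNA-binding protein of germ cells, with 13.6 ± 10.1 against 0.108 ± 0.114 CPM. The fitted ratio of Rbm44 was 293-fold without WT1 and 78.0-fold without KO1, and all 8 WT counts of Adgrg7 were in WT2. Gja1, which encodes the gap junction protein connexin 43, rose 21.2-fold, Mmrn1 23.6-fold (14.3-fold without KO1), Il31ra 19.4-fold (45.8-fold without WT1), the integrin subunit gene Itga2 15.1-fold, Cavin2 14.7-fold (33.8-fold without WT1) and Csf1r, the receptor for macrophage colony-stimulating factor, 13.3-fold (6.67-fold without KO1). The largest falls were in genes that were expressed in WT and close to 0 in KO. Slc4a10, a bicarbonate transporter, had 13.1 ± 1.13 CPM in WT and no count in KO, at least 574-fold lower. Zfp979 and Mtus2 had 1 count over the KO group, with WT to KO ratios of 2054 (95% exact counting interval 368 to 81156) and 1428 (256 to 56428). Omg was 443-fold lower, with 4 of its 5 KO counts in KO1, and the germ cell gene Asz1 302-fold, with all 12 of its KO counts in KO2. Rnf17, another germ cell gene, was 42.4-fold lower, Xist 96.9-fold (333-fold without KO1), Mtmr7 67.8-fold, Gkn3 57.1-fold, Crisp3 56.2-fold (29.0-fold without WT1), Chil4 45.3-fold (25.3-fold without WT1) and Rps4l 44.9-fold. Reads of Rps4l, Crisp3, Chil4 and Zfp979 can be shared with near-identical family members, and how the counting treated them is not given in the sources used here.

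The groups did not overlap in 28.0% of tested genes. Chance alone gives 10% on average, but genes vary together, so the share in a single split can lie far from that. It was not measured in other splits, so no excess over chance is claimed. The counts of calls depended on the libraries included. Higher and lower genes numbered 13 and 29 without WT3, 38 and 53 without KO3, 47 and 63 without KO1, 68 and 128 without WT2, and 108 and 148 without WT1, while 371 and 247 were called without KO2. DESeq2's Wald test called 1075 and 920. On simulated data it made 47 false calls where edgeR made 2, and recovered 62.7% of genes changed 2-fold where edgeR recovered 49.3%. Of the 65 named genes past the test, 13 stayed past it in all 6 fits that left out 1 library, namely Cd74, Ddx3y, Eif2s3y, Gkn3, Itga2, Kdm5d, Mtmr7, Mtus2, Omg, Rnf17, Slc4a10, Uty and Zfp979. None of the 65 changed sign in these fits.

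Genes of glycolysis were lower in the libraries labelled KO. Of 23 measured members of the list, 8 fell, 0 rose and 15 did not pass the test over all genes. The 8 included enzymes of the lower part of the pathway, with Eno1 at 412 ± 26.6 CPM in KO against 814 ± 71.7 in WT (log2 fold change −0.98 ± 0.09, adjusted p = 0.00675) and Pgam1 at 51.3 ± 4.74 against 105 ± 7.90 CPM (−1.03 ± 0.11, adjusted p = 0.00963). Slc16a3, which encodes the lactate exporter MCT4, was 60.3% lower (−1.33 ± 0.18, adjusted p = 0.0204), and Aldoa 28.9% lower (−0.49 ± 0.08, adjusted p = 0.0281). Chosen after their values were seen, the other genes that fell were Pfkp (53.5% lower), Slc2a1, which encodes the glucose transporter GLUT1 (41.6%), Pgk1 (28.7%) and Ldha (25.2%), at adjusted p-values between 0.0303 and 0.0438. Adjusted over the list alone, 14 members fell and 2 rose, the latter, also named after their values were seen, being Hk1 and Pfkm. The median log2 fold change of the list was −0.42, with quartiles of −0.88 and −0.00, and camera with a preset correlation gave an adjusted p of 1.02e-07. With an estimated correlation the adjusted p was 0.202, and fry, which tests whether the genes of a list move 1 way on balance, gave 0.0136. No single member among the 4 examples stayed past the gene test in every fit without 1 library: Eno1 reached an adjusted p of 0.0566, Pgam1 0.0536, Slc16a3 0.0794 and Aldoa 0.127 at most.

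**Figure D2:**
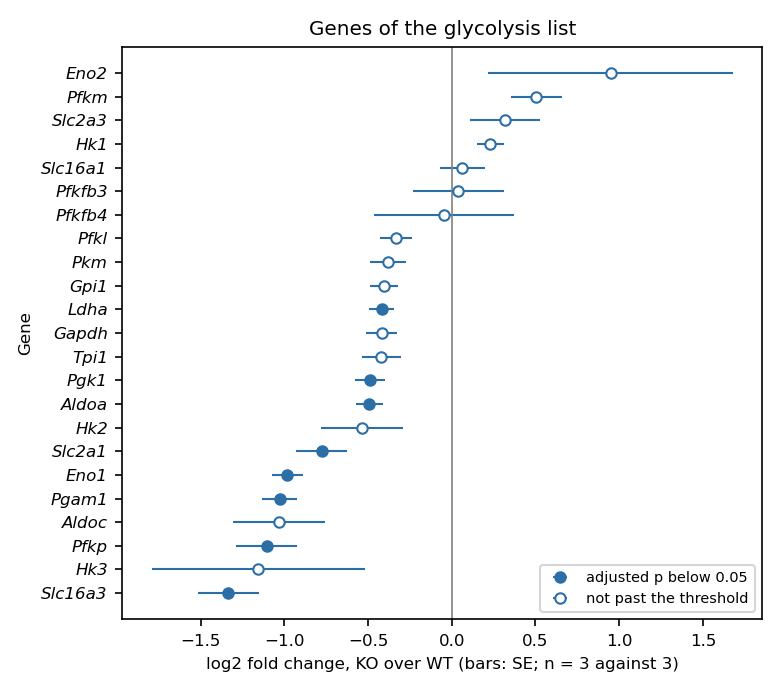
Log2 fold change of each measured gene of the glycolysis list, KO over WT, with its SE (3 against 3 libraries), filled where the adjusted p was below 0.05. The 8 filled genes lie between −1.33 for Slc16a3 and −0.42 for Ldha, and 6 of the 23 genes lie above 0.

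Lists of genes for protein synthesis and folding were lower as well. Of 30 genes of ribosome biogenesis and MYC targets 3 fell, Ddx21 by 29.4%, Rrp12 by 28.1% and Ipo4 by 31.5%, and 29 of 30 had a negative log2 fold change (median −0.31, camera adjusted p = 8.11e-08, 14 lower adjusted over the list alone). With an estimated correlation the adjusted p of that list was 0.624, and fry gave 0.121. Of 21 genes of the unfolded protein response 4 fell and 9 were lower adjusted over the list alone (median −0.26, camera adjusted p = 1.83e-05, adjusted p = 0.599 with an estimated correlation, fry 0.0525). Xbp1, a transcription factor of that response, was at 160 ± 15.4 CPM in KO and 331 ± 76.5 in WT, Hspa5, the chaperone BiP, was 22.0% lower, Sdf2l1 24.3% lower and Creld2 27.2% lower. Cytosolic ribosomal protein genes differed little, with a median log2 fold change of −0.18 over 45 genes and 0 past the gene test over all genes or over the list alone (camera adjusted p = 2.59e-04, adjusted p = 0.702 with an estimated correlation). The member with the smallest p was Rplp1, at 386 ± 45.7 against 507 ± 53.8 CPM with an adjusted p of 0.112.

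Among immediate early genes, transcription factors and other genes induced within minutes of a stimulus, 5 of 20 fell, namely Egr1 (76.4% lower, 29.1 ± 1.26 against 123 ± 43.9 CPM), Ier2 (35.1%), Junb (32.0%), Nr4a2 (54.6%) and Fosl2 (54.7%). The median was −0.49 (camera adjusted p = 0.00179, 8 lower and 1 higher adjusted over the list alone), and the adjusted p was 0.624 with an estimated correlation and 0.0656 without KO2. In the cholesterol synthesis list 2 of 24 genes fell, Lss by 34.1% and Cyp51 by 30.1%, with a median of −0.23 and, adjusted over the list alone, 5 lower and 1 higher. Its camera adjusted p was 0.00602, against an adjusted p of 0.615 with an estimated correlation and 0.0546 without KO2. Granule genes of immature myeloid cells had a median of −0.94 with 0 of 14 past the gene test over all genes or over the list alone. Their camera adjusted p was 0.0175, against an adjusted p of 0.624 with an estimated correlation, 0.239 without WT1, 0.0628 with a filter of at least 1 CPM in 3 libraries and 0.418 with an erythroid covariate added after seeing the data, where the median was −0.35 (quartiles −0.93 and 0.29, against −1.25 and −0.02). Serpinb1a was at 205 ± 45.5 against 349 ± 90.2 CPM and Cd63 at 150 ± 58.0 against 286 ± 60.9 CPM.

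Lists of the cell cycle and of the erythroid lineage were higher in the libraries labelled KO. The groups overlapped in the mean log2 CPM of 2 of these lists. KO2 lay slightly below WT2 for the E2F list (7.22 against 7.25) and further below it for the erythroid list (8.21 against 8.74). Overlap of the G2/M list as a whole was not examined. Its genes Cenpf, Kif11, Top2a and Mki67 did not overlap between the groups, nor did E2f1 of the E2F list. Of 35 E2F targets and replication genes 33 had a positive log2 fold change (median 0.35, camera adjusted p = 2.83e-07, adjusted p = 0.624 with an estimated correlation), but only E2f1 rose, 1.73-fold, over all genes and over the list alone. Of 30 genes of G2/M and mitosis Cenpf, Kif11 and Top2a rose, 1.41-fold, 1.39-fold and 1.37-fold, and 8 were higher adjusted over the list alone (median 0.29, camera adjusted p = 2.48e-05, adjusted p = 0.624 with an estimated correlation). The proliferation marker Mki67 stood at 525 ± 126 against 269 ± 61.0 CPM, with an adjusted p of 0.0608. Erythroid markers had a median of 1.5, 0 of 20 passed the gene test over all genes or over the list alone, and their levels varied within both groups. Their camera adjusted p was 5.60e-06, and the adjusted p was 0.624 with an estimated correlation. Globin transcripts took 1.84%, 0.639% and 2.03% of the counts in KO1, KO2 and KO3, and 0.174%, 0.829% and 0.452% in WT1, WT2 and WT3. With the mean log2 CPM of the erythroid markers as a covariate, a fit chosen after seeing the data, the adjusted p of the E2F list was 0.296 and that of the G2/M list 0.169, and 135 genes were higher and 90 lower. In that fit the E2F median was 0.08 (quartiles −0.04 and 0.17, against 0.27 and 0.45 without the covariate) and the G2/M median 0.07 (−0.05 and 0.23, against 0.13 and 0.45). Cenpf, Kif11, Top2a and E2f1 had log2 fold changes of 0.57, 0.36, 0.37 and 0.48 in it, against 0.50, 0.48, 0.45 and 0.79, and none of the 4 passed the test. Of 26 genes of the stem cell and leukaemia programme 3 rose: Kit, the stem cell factor receptor, 3.64-fold, Cd27 8.02-fold and Hoxa10 2.19-fold. This list had a median of 0.25 and, adjusted over the list alone, 4 higher and 1 lower. Its camera adjusted p was 0.0310, against an adjusted p of 0.624 with an estimated correlation, 0.114 without WT2, 0.218 without KO2 and 0.0679 with a filter of at least 1 CPM in 3 libraries. Hoxa9, a part of which is in the NUP98-HOXA9 fusion, was 23.5% lower with an adjusted p of 0.0502.

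Markers of lymphoid cells and macrophages were higher in the libraries labelled KO. Of 20 measured T and NK cell markers 7 rose, and 16 were higher and 1 lower adjusted over the list alone (median 4.10, camera adjusted p = 5.38e-11, adjusted p = 0.534 with an estimated correlation, fry 0.0525). Only 4 of the 20 had a WT mean of at least 1 CPM, so the median rests largely on ratios over low WT values. Gzmb, chosen after its value was seen, was abundant in both groups, at 828 ± 285 against 507 ± 78.6 CPM with an adjusted p of 0.155. Cd3d had 2.26 ± 1.22 CPM in KO and 0.132 ± 0.0608 in WT, Cd3e 2.14 ± 1.00 and 0.0264 ± 0.0458, Trbc1 2.17 ± 1.23 and 0.0574 ± 0.0681, and Trbc2 3.27 ± 1.85 and 0.154 ± 0.158. Cd3e, Trbc1 and Trbc2 had 4, 8 and 22 counts over the WT group, of which 4 were in WT1, 6 in WT3 and 16 in WT2. Trbc1 and Trbc2 are near-identical, so reads could be split between them. With the erythroid covariate the median of the T and NK list was 2.98, with a lower quartile of 1.52 and a camera adjusted p of 1.95e-06. Cd3d, Cd3e, Trbc1 and Trbc2 did not pass the gene test in that fit. Of 12 B cell and plasma cell markers 3 rose, Cd79b and Blk among them, and 4 were higher adjusted over the list alone (median 2.41, camera adjusted p = 1.02e-07, adjusted p = 0.202 with an estimated correlation, fry 0.0136). Of these 12 markers 5 had a WT mean of at least 1 CPM. Cd79b was 5.12-fold higher, and Igkc, the immunoglobulin kappa constant region, was at 45.6 ± 20.4 against 5.63 ± 5.90 CPM with an adjusted p of 0.0804. WT2 had 12.4 CPM of Igkc against 1.88 and 2.59 in WT1 and WT3, and without WT2 the ratio was 20.4-fold with an adjusted p of 0.0269. Of 13 dendritic cell markers the antigen presentation genes Cd74, H2-Aa and H2-Eb1 rose 8.13-fold, 9.16-fold and 3.70-fold (median 2.06, camera adjusted p = 2.43e-07, adjusted p = 0.282 with an estimated correlation, fry 0.0136, 8 higher and 1 lower adjusted over the list alone). Of 23 macrophage markers Csf1r, Mrc1 and Cx3cr1 rose 13.3-fold, 9.28-fold and 2.74-fold (median 1.90, camera adjusted p = 2.30e-06, adjusted p = 0.624 with an estimated correlation, fry 0.143, 12 higher and 2 lower adjusted over the list alone). Csf1r was at 26.7 CPM in KO1, 8.08 in KO2 and 5.38 in KO3, while Cx3cr1 was lowest in KO1 of the KO libraries, with 46.7 CPM against 66.7 and 66.8, and Mrc1 was highest in KO2, with 4.88 CPM.

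**Figure D3:**
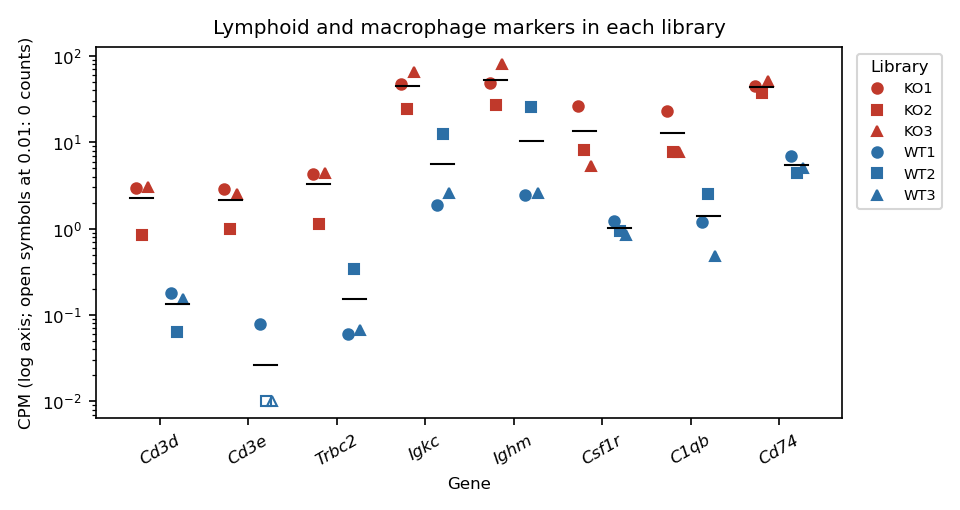
Level of lymphoid, macrophage and antigen presentation genes in each library, in CPM on a log axis, with a symbol per library, a bar at each group mean and open symbols for 0 counts. Cd74 shows 44.4 ± 6.69 CPM in KO and 5.46 ± 1.34 in WT, and the plotted T cell genes Cd3d, Cd3e and Trbc2 stay below 5 CPM in all libraries.

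Marker lists of neutrophils, megakaryocytes, mast cells and stroma did not pass the set test with all 6 libraries. Without 1 library the neutrophil list was lower at camera adjusted p-values of 4.57e-04 (KO1), 0.0263 (WT2) and 0.0305 (WT3), and the mast cell list at 0.00543 (KO3) and 0.0378 (WT3). Neutrophil markers had a median of −0.94 with 0 of 22 past the gene test (camera adjusted p = 0.136), and Ngp was at 2.32 ± 3.18 CPM in KO and 129 ± 140 in WT. The log2 fold change of Ngp was −5.80 with all libraries, −4.41 without WT1 and −8.07 without KO1. Of 16 megakaryocyte and platelet markers Vwf rose, with 409 ± 133 CPM in KO and 151 ± 25.5 in WT, and Pf4 fell by 68.1% (median −0.16, mean 0.06, downward test, camera adjusted p = 0.726). Of 16 mast cell, basophil and eosinophil markers Hdc, which encodes the histamine-forming enzyme, fell by 73.0% (median −0.03, camera adjusted p = 0.0912), and Siglecf was at 14.2 ± 5.26 against 56.0 ± 27.9 CPM. Of 9 stromal and endothelial markers Vim, which leukaemia cells also express, rose 2.59-fold (median 0.42, camera adjusted p = 0.208).

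The lists of taurine handling and of amino acid sensing did not pass the set test. Of 33 genes of mTORC1 and amino acid sensing Fnip1, a partner of folliculin, fell by 66.3% and Sesn1, a sestrin, rose 1.40-fold. The list's median was −0.07 and its mean 0.06, with a camera adjusted p of 0.615. Of 9 genes of taurine synthesis and handling Csad, the decarboxylase that forms hypotaurine, rose 2.05-fold, from 10.8 ± 1.20 CPM in WT to 22.1 ± 3.78 in KO (adjusted p = 0.0367). Csad passed in 0 of 6 fits without 1 library, with an adjusted p of 0.123 at most. It passed neither with the replicate number as a block (0.132) nor with the erythroid covariate (0.0702). The median of this list was −0.05 while its mean was 0.19 and its test pointed upwards, with a camera adjusted p of 0.686. The osmotic stress list (median 0.12, camera adjusted p = 0.208) held 1 gene that rose, Hspa1b, and the amino acid transporter list (median −0.00, mean 0.26, upward test, 0.677) held 1, Slc36a4.

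The remaining lists did not pass camera with all 6 libraries either, though 6 of them passed without 1 of these. For energy metabolism the medians and camera adjusted p-values were −0.07 and 0.215 for the TCA cycle, where Pcx fell by 60.4%, −0.03 and 0.407 for nuclear genes of oxidative phosphorylation, 0.01 and 0.965 for mitochondrially encoded genes, whose test pointed downwards, −0.03 and 0.914 for fatty acid oxidation, and −0.03 and 0.658 for fatty acid synthesis, the mean of which was 0.02. For stress responses they were −0.14 and 0.0912 for the integrated stress response, where Cebpb fell by 75.1% and Gars by 23.0% and the list was lower at 0.0183 without WT1, 0.0284 without KO1 and 0.0369 without KO3, −0.27 and 0.261 for heat shock (mean 0.10, with Hspa1b up and Hspa8 down), −0.10 and 0.244 for hypoxia, where Slc2a1 fell, and 0.16 and 0.215 for NRF2 targets, where Nqo1 rose 1.86-fold. Values of 0.16 and 0.243 were found for lysosome and autophagy, where Ctsz fell, −0.02 and 0.615 for apoptosis regulators, where Bcl2l1 rose, and 0.06 and 0.677 for p53 targets, whose mean was −0.09 and in which Sesn1 rose and Perp and Plk3 fell. For signalling lists they were −0.11 and 0.244 for STAT5 targets, where Il2ra, Socs1 and Socs2 fell and Bcl2l1 rose, −0.12 and 0.244 for NF-kB and inflammatory genes, where Ccl3 fell, 0.33 and 0.470 for interferon-stimulated genes, which were lower at 1.03e-04 without KO1 and higher at 0.0129 without KO2 and 0.0458 without KO3, and 0.40 and 0.244 for Wnt targets, where Tcf7 rose. Genes named in this paragraph, and Blk, Fosl2, Hspa1b and Slc36a4 above, were chosen after their values were seen, since few members of their lists passed the test.

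**Figure D4:**
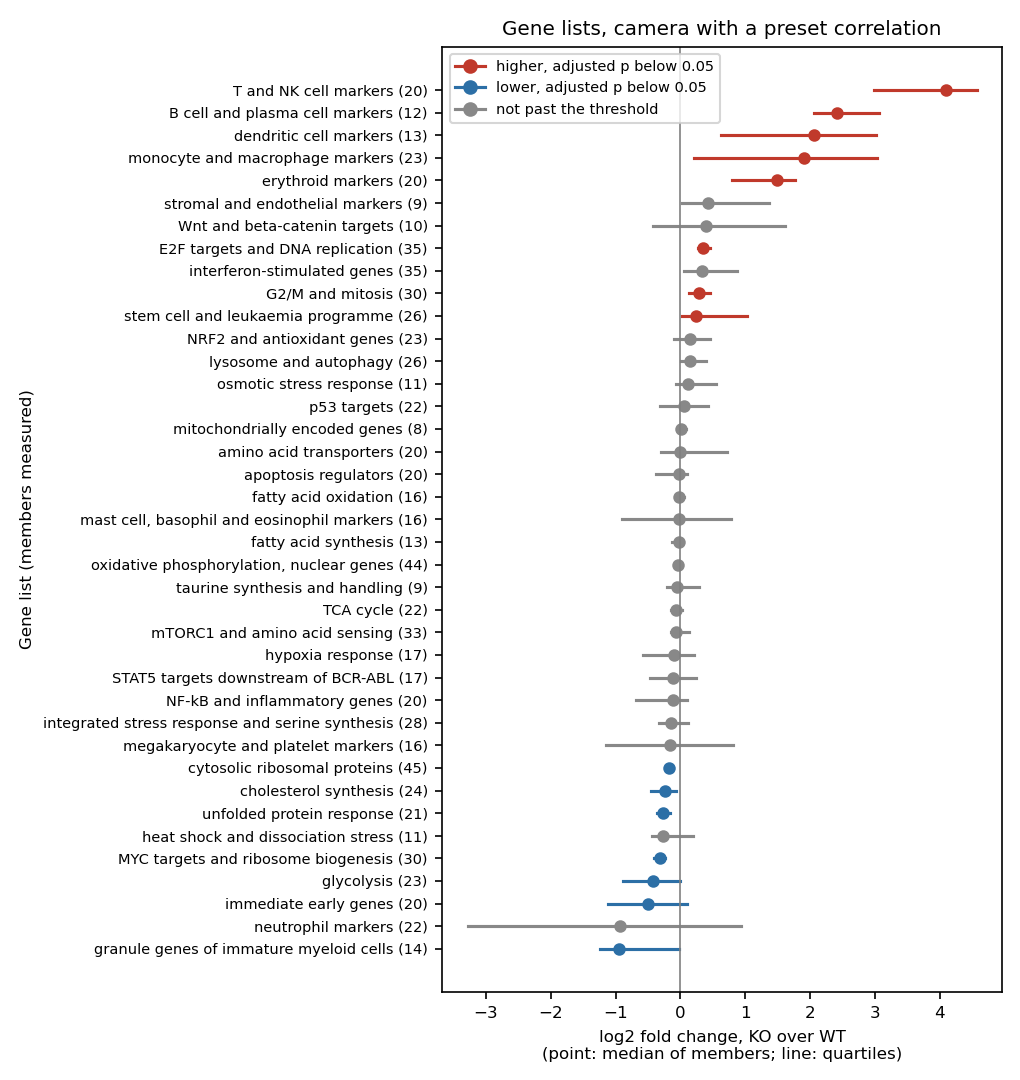
Median log2 fold change, KO over WT, of the measured members of each of 39 gene lists, with the quartiles as a line and the number of measured members in brackets, coloured by camera's call with a preset correlation. Lists of T and NK, B, dendritic and macrophage markers lie highest, with medians from 4.10 to 1.90, and the glycolysis list lies at −0.42. Most T and NK and B cell markers had a WT mean below 1 CPM.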

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

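The fits with the erythroid covariate and without X and Y genes were chosen after seeing the data, and the causes of the changes below were not tested. Against 250 higher and 293 lower genes, DESeq2's size factors, upper-quartile scaling, limma-voom, both other filters and the removal of X and Y genes gave counts within 1.5 times. DESeq2's Wald test gave 1075 and 920, with all 543 genes among them, and the erythroid covariate 135 and 90, with 138 of the 543. The labels do not say whether same-numbered libraries are paired. Deviations from the group means correlated at 0.06, −0.14 and −0.07 between same-numbered libraries, and WT2 went best with KO3 (0.19). With 3 libraries in a group these correlations cannot exclude a pairing. The fit with the replicate number as a block (replicate block) gave 8 and 20, of which 25 were among the 543. It leaves fewer residual degrees of freedom. Leaving out 1 library gave 13 to 371 higher genes and 29 to 247 lower genes, with the lowest counts without WT3 and the highest number of higher genes without KO2. Calls were 46.0% higher genes, against 28.6% with the block, 34.7% without WT2, 31.0% without WT3, 60.0% without KO2 and 60.0% with the erythroid covariate. No scaling moved the median of all genes by over 0.1. Slc6a6 stayed between −0.20 and −0.14 in log2 fold change and did not pass in any of 16 fits. Of the 65 named genes past the test, 14 passed without WT3, 48 without KO2, 13 with the block and 29 with the erythroid covariate.

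With an estimated correlation camera called 0 higher and 0 lower lists, with 3 of 39 at an unadjusted p below 0.05, against 8 and 7 with the preset correlation. Fry called 2 higher lists, B cell and dendritic, and 1 lower, glycolysis, and no other list passed it. Leaving out 1 library gave 5 to 11 lower lists, with 11 without KO1 and 5 without KO2. The glycolysis, T and NK, B cell, dendritic, macrophage, MYC, unfolded protein response and ribosomal protein lists passed in the same direction in all 15 fits with the preset correlation, glycolysis at adjusted p-values between 6.00e-11 and 3.47e-06. The stem cell and granule lists lost their call with at least 1 CPM in 3 libraries (0.0679 and 0.0628), where the mast cell list gained one (0.0407). With the block the neutrophil (1.94e-05) and mast cell (0.0347) lists were lower, and without a filter the integrated stress response (0.0220). With the erythroid covariate E2F (0.296), G2/M (0.169) and granule (0.418) lists were no longer called. Nor was the erythroid list (0.872), which is the source of the covariate, so that its loss was fixed in advance. In this fit the integrated stress response (1.30e-04) and oxidative phosphorylation (8.89e-04) were lower and osmotic stress (0.0162) higher. Without 1 library, lists gained calls for oxidative phosphorylation (WT1, 0.0222), NF-kB (WT2, 0.0275, and KO1, 0.0473), interferon (higher without KO2, 0.0129, and KO3, 0.0458), lysosome (KO2, 0.0478) and NRF2 (KO2, 0.0222). Directions turned only for lists that camera with the preset correlation and all libraries did not call. With the erythroid covariate these were amino acid transporters (adjusted p = 0.493), fatty acid oxidation (0.594), interferon-stimulated genes (0.416), megakaryocyte markers (0.276) and NRF2 targets (0.418), and with fry mitochondrially encoded genes (0.974). Without 1 library the direction turned at least once for fatty acid oxidation (adjusted p-values over these fits 0.410 to 0.973), interferon-stimulated genes (1.03e-04 to 0.691), megakaryocyte markers (0.181 to 0.960), mitochondrially encoded genes (0.468 to 0.996), NF-kB genes (0.0275 to 0.992), oxidative phosphorylation (0.0222 to 0.918), p53 targets (0.201 to 0.824) and taurine handling (0.437 to 0.966). The interferon list was lower at 1.03e-04 without KO1. Pseudocount alternatives were not run, since the values are counts. Depth limits genes near 0.07 CPM, which is 3 counts in a library.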

Other observations

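The tests that weigh explanations, the sample splits and the single genes of the next 2 paragraphs, apart from Hoxa9, were chosen after the results they bear on were seen.

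Single genes, chosen by hand and not as a tested group, differed in both directions. Dazl, an RNA-binding protein of germ cells, was at 18.5 ± 3.60 CPM in the libraries labelled WT and 1.54 ± 0.571 in those labelled KO (SD, n = 3, edgeR adjusted p = 0.00716). Ddx4, a helicase of germ cells, went the other way, with 15.8 ± 3.68 CPM in KO and 2.57 ± 1.83 in WT (adjusted p = 0.0425). Apoa1, the main protein of high-density lipoprotein, was at 644 ± 76.8 CPM in WT and 24.4 ± 14.5 in KO (adjusted p = 0.0139). The milk protein gene Csn2 was at 18.6, 6.64 and 3.67 CPM in WT1, WT2 and WT3 and at 0.105 ± 0.163 CPM in KO (adjusted p = 0.0391). Prdm16, a transcription factor of stem cells and brown fat, was 41.9-fold lower in KO (adjusted p = 7.31e-04).

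Of the genes whose human or mouse forms make up the leukaemia's fusions, Bcr fell and the other 3 had lower values in KO that did not pass the test. Bcr was at 61.1 ± 5.52 against 95.5 ± 7.39 CPM (adjusted p = 0.0281), Abl1 at 125 ± 4.53 against 154 ± 11.4 (0.0986), Nup98 at 186 ± 26.2 against 272 ± 47.3 (0.0961) and Hoxa9 at 102 ± 5.63 against 134 ± 5.73 (0.0502), with no overlap between the groups for any of the 4. Counts per gene do not separate reads of the fusion transcripts from those of the mouse genes. Of X-linked genes with a Y-linked partner, Eif2s3x was 1.68-fold higher in WT (adjusted p = 0.0249), while Kdm5c, Ddx3x and Kdm6a were 1.18-fold, 1.16-fold and 1.21-fold higher with adjusted p-values of 0.147, 0.213 and 0.330.

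Lower glycolysis genes were weighed against technical explanations. With the erythroid content of the libraries as a covariate the list's median log2 fold change was −0.39 (quartiles −0.54 and −0.21), against −0.42 without it. This argues against erythroid content as the whole cause. Camera's adjusted p at the preset correlation was 3.47e-06 in that fit, but this test also called the list in 5 other splits of the libraries. The content of T cells, B cells and macrophages was not weighed in this way. After removal of trends with GC content and transcript length, known for all 23 members, the median was −0.48 with an upper quartile of −0.11, which argues against such a trend as well. Donor sex or parent leukaemia cannot be told apart from the label, since sex-linked expression followed it in 6 of 6 libraries and no comparison within a sex can be made. The genotype that the labels name was not tested apart from these and stays open.

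Higher T cell, B cell and macrophage markers may come from normal cells of these types in the sorted cells, which the sort for leukaemia cells should remove. Within the KO libraries, 17 of 20 measured T and NK cell markers were lowest in KO2, while 19 of 23 macrophage markers were highest in KO1 and 7 of 12 B cell markers were lowest in KO2. This order is not particular to T cells, since KO2 was also lowest of the KO libraries for the erythroid score (8.21 against 9.66 and 9.83), globin (0.639% against 1.84% and 2.03%) and the E2F score (7.22 against 7.55 and 7.66). A lower share of leukaemia cells against all other types would raise neutrophil markers alike only if the leukaemia cells themselves lacked them. Neutrophil markers had a median of −0.94 with an upper quartile of 0.93. This lies below the lower quartiles of 2.98 for T and NK and 2.06 for B cell markers, but overlaps that of 0.21 for macrophage markers. Whether the leukaemia cells express neutrophil markers cannot be seen here, so the comparison leaves a lower share open for each of these lists. Donor sex or parent leukaemia cannot be told apart from the label (6 of 6 libraries).

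Genes with a large difference between the groups, defined by an absolute log2 fold change of at least 4 and an adjusted p below 0.05, numbered 101. Of these 56 were higher in KO and 45 higher in WT. The lower group was not always near 0, as Apoa1 had 24.4 ± 14.5 CPM in KO. Location on the sex chromosomes as the whole cause is argued against, since 90 of the 100 with a known chromosome are autosomal, 5 lie on X and 5 on Y. Of the 101, 0 were among the 100 tested genes nearest to Slc6a6, which argues against alleles carried within that stretch and acting on their own genes. Of those 100 genes 2.0% passed the test against 3.56% of all genes (Fisher exact p = 0.588), too few calls to show a small difference. A longer carried stretch was not tested and stays open. Of the 56 higher in KO 10 are in a fixed list, 7 of them T and NK cell markers and 2 B cell markers. Of the 45 higher in WT 0 are in a list, which says little, since the lists hold 870 genes against 15232 tested. Donor sex, donor or parent leukaemia may underlie them, autosomal genes included, and cannot be told apart from the label, with sex-linked expression following it in 6 of 6 libraries.

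The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 250 higher and 293 lower genes, and the most that any other split called in a direction was 1, so that 1 of 10 splits gave as many. For gene lists the real split called 15 and another called 19, that of KO1, KO3 and WT1 against the rest, and 4 of 10 splits called at least 15. Each other split mixed the labels unevenly, so it kept part of the label difference and put the rest into the spread within its groups. The low gene counts elsewhere were therefore partly fixed in advance, and a list called elsewhere may still follow the label. At the preset correlation the test called at least as many lists in some of these mixed splits as in the real one. The glycolysis list had a median of 0.42 in size in the real split and 0.25 at most in the others, where its lowest adjusted p was 0.00917 against 1.02e-07, and it passed the test in 5 of them. The real split also gave the smallest camera p for the T and NK, B cell, dendritic and unfolded protein response lists. For each other called list another split gave one as small or smaller. The lowest adjusted p elsewhere was 7.14e-17 for E2F, against 2.83e-07, and 4.56e-43 for erythroid markers, against 5.60e-06. Medians larger in size were seen elsewhere for the erythroid (1.89), ribosomal protein (0.185) and immediate early (0.532) lists.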
